A study of Mus musculus with 8 samples.

How the data were processed

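The series measured gene expression in CD103+ CD11b+ cDC sorted by flow cytometry from mouse mesenteric lymph nodes. Per the labels' protocols, RNA was extracted from sorted cells, and 2.5 ng was reverse transcribed with a whole-transcriptome amplification kit; the label was biotin. The values are the deposited log2 values per probe set, made with RMA in Partek per the submitters' processing notes, which name no versions. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a set. As the distributions are made alike, a shift of all genes in the same direction would not be seen. Differences of very bright probe sets, near the top of the scale, can be compressed. The order of the steps, any filter on probe sets and the genome build are not given in the sources used here, so no coordinates are printed.

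The 8 arrays were grouped by the genotype in the labels, 4 wild type and 4 hBcl-2 transgenic. An array holds a pool of 2 to 3 samples, and the pool is the replicate. Arrays have no read depth, and precision is set by the 4 arrays of a group and by how far a probe set lies above the dim end of the scale. No column of values was left out.

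Probe sets were named through the platform's annotation. Of 34390 probe sets, 23521 name 1 gene, 1814 name several and 9055 name none there. Only the first kind was tested, and 23328 of these had a gene number found in a table of mouse genes for the assembly GRCm38.p6, which was used for names and for the order of neighbouring genes. It changed 0 symbols. For the 1082 genes with several probe sets, the set with the highest mean over all 8 arrays was used, which left 22180 genes. No filter on signal was applied.

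The comparison was transgenic minus wild type, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors are the SD over the arrays of a group or the moderated SE of the difference, and intervals are 95% intervals from the same fit. A gene is said to have risen, fallen or changed only past that threshold. Genes at an unadjusted p below 0.05 with a change of at least 1.5-fold were counted as a description.

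The groups, the tests, the alternatives, 38 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered apoptosis, cDC identity, maturation, antigen presentation, innate signalling, metabolism, stress responses, markers of 12 other cell types and sex-linked transcripts. The 36 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each was also tested with an estimated correlation, with fry, and with an exact two-sided permutation test of the list's mean (70 assignments, smallest p 0.0286). Members were also adjusted over the list alone. None of the lists was chosen on these samples.

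The rule allowed the text to name the members of the pro-survival and pro-apoptotic BCL2 family, the genes of the sorting markers and of the transgene's promoter, and the 12 genes with the largest rise and the 12 with the largest fall past the threshold. Predicted genes, small RNAs and olfactory or vomeronasal receptors were counted but not named. From each list it took up to 6 members past the threshold and the 2 members with the highest and the 2 with the lowest moderated statistic. Other genes named in the closing section were chosen after their values were seen.

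The procedure was tested on simulated data with the real genes' means and spreads. With 200 of 22180 genes changed in each of 20 simulations of this comparison, limma recovered 30.1% of genes changed 1.5-fold, 75.6% of genes changed 2-fold and 93.6% of genes changed 3-fold, and 4.19% of its calls were false. Camera found a shifted list in 20 of 20 simulations and called 1 of 660 unshifted lists. The simulated genes varied independently, which real genes do not.

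The alternatives were other variance moderation (trended, trended and robust, none), filters on dim genes, quantile normalization applied again, centring of each array on its median, the mean over the probe sets of a gene, every probe set on its own, array weights, the replicate number as a block, other thresholds and leaving out each array in turn. Block fits and array weights used limma with statmod 1.5.0. The 35 divisions of the 8 arrays into 4 and 4 were refitted to see how often a result as large arises. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.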

Results

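Gene expression was measured on 8 microarrays of CD103+ CD11b+ conventional dendritic cells (cDC), antigen-presenting cells that carry antigen from the intestine to its draining lymph nodes. The cells were sorted from the mesenteric lymph nodes of 8-week-old male C57BL6 mice on chow diet. Of the arrays, 4 came from mice that carry human BCL2 under the promoter of CD11c (the hBcl-2 transgene) and 4 from wild-type littermates. BCL2 blocks the mitochondrial pathway of apoptosis, and CD11c is a surface integrin of dendritic cells, so the comparison asks how these cells differ when the transgene is expressed in them. Each array holds a pool of 2 to 3 samples, and n = 4 pools per group throughout. The labels do not say which animals went into which pool, so the tests measure the spread between these pools. The number of arrays limits the precision of each value.

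The deposited log2 values ran from 2.11 to 13.95, and the median over probe sets lay between 5.05 and 5.15 on every array. The wild-type arrays were alike, with a mean correlation of 0.986 to 0.988 with the other arrays of their group. The transgenic arrays varied more, and transgenic replicate 4 stood apart, with a mean correlation of 0.974 with its group against 0.980 to 0.983 for the other 3. Its values were also spread less widely, with an SD over probe sets of 2.00 against 2.07 to 2.11 on the other 7 arrays. The Y-linked transcript Eif2s3y was bright on all 8 arrays (9.06 to 9.83) and Xist was dim (3.73 to 4.48), as male samples show.

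**Figure D1:**
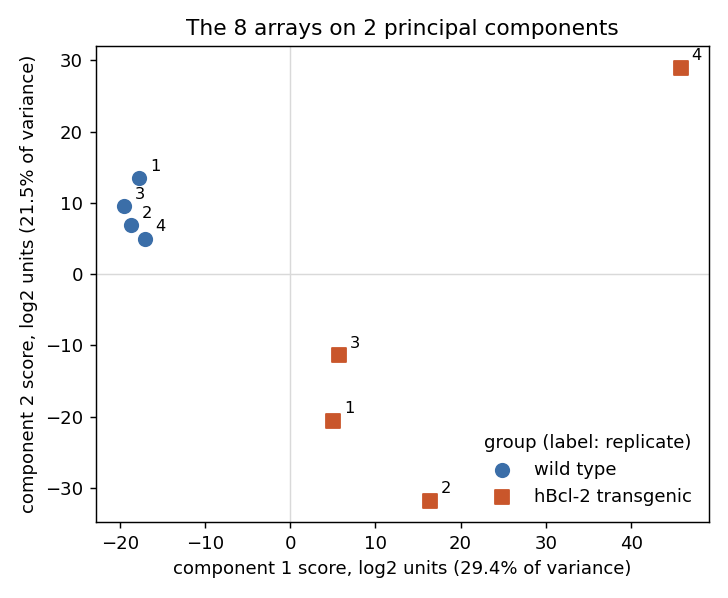
Scores of the 8 arrays on the first 2 principal components of all genes (log2 units), which hold 29.4% and 21.5% of the variance. Circles are wild-type arrays, squares are hBcl-2 transgenic arrays, and numbers are replicates; the wild-type arrays lie together, and transgenic replicate 4 lies at 45.8 on component 1, away from the other transgenic arrays.

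The array did not check the genotype labels. Its probes are made for mouse Bcl2, and the transgene is human. The brighter of the Bcl2 probe sets gave 6.11 ± 0.40 (SD, n = 4) in wild-type and 6.86 ± 0.34 (SD, n = 4) in transgenic arrays, a difference of 0.74 (SE 0.22) that did not pass limma's test over all genes (adjusted p = 0.139). Only 2 of the 4 transgenic arrays lay above every wild-type array. The dimmer probe set gave 4.08 and 4.06. Itgax, which encodes CD11c, differed by 0.17 (adjusted p = 0.705 by limma). The genes of the other sorting markers, Itgae (CD103) and Itgam (CD11b), were dim in both groups, with levels of 5.66 and 5.40 for Itgae and 5.57 and 5.58 for Itgam, and neither passed.

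Among the genes with the largest changes, Npy1r, Mmp7 and Sox4 rose in transgenic cDC, and Cxcl1, Tnfsf9, Ebi3, Tnf and Cd40 fell. Npy1r, the Y1 receptor for neuropeptide Y, rose 14.4-fold, from 5.46 ± 0.27 to 9.30 ± 0.47 (SD, n = 4; limma adjusted p = 7.00e-05). Its wild-type level was dim, where signal is hard to tell from background, so the size of this fold is uncertain. Mmp7, the matrix protease matrilysin, rose 7.51-fold, from 8.67 ± 0.27 to 11.58 ± 0.24 (SD, n = 4; limma adjusted p = 7.00e-05). With the mean over the probe sets of Mmp7 its log2 fold was 1.57 (adjusted p = 0.0116 in limma), against 2.91 on the probe set with the highest mean. The chemokine gene Cxcl1, whose product attracts neutrophils, fell by 1.88 on the log2 scale (SE 0.20; limma adjusted p = 0.00256). The size of this fall is uncertain, since its transgenic level of 5.86 was near the dim end. Tnfsf9, which encodes the costimulatory 4-1BB ligand, fell by 1.87 on the log2 scale (SE 0.16; limma adjusted p = 0.00101).

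Of 22180 genes tested, 374 passed, 186 higher and 188 lower in transgenic arrays, of which 67 and 52 changed at least 2-fold. The 4 arrays of each group did not overlap for 373 of the 374. Over all genes, 8.94% had groups that did not overlap, against 2.86% by chance, and 2919 genes had an unadjusted p below 0.05 in limma, against 1109 by chance. At an unadjusted p below 0.05 and a change of at least 1.5-fold there were 919 genes, 479 higher and 440 lower. Among the 374, 13 higher and 15 lower genes are predicted genes, small RNAs or receptors of the families left unnamed.

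The next genes by size of rise were an immunoglobulin kappa variable segment (log2 fold 2.70, SE 0.41), Cdh2, which encodes N-cadherin (2.65, SE 0.35), Ephx1, the microsomal epoxide hydrolase (2.24, SE 0.22), and Il18r1, a chain of the interleukin 18 receptor (1.94, SE 0.20). The transcription factor gene Sox4 rose from a wild-type level of 8.08 ± 0.15 (SD, n = 4) by 1.91 (SE 0.16). Ccpg1os, Scara3, Ceacam15, BC051142 and AB010352 rose by 1.59 to 1.92. The wild-type levels of the kappa segment (4.85), Ephx1 (5.03), Scara3 (5.49), BC051142 (4.50) and AB010352 (3.60) were dim too. Those of Ceacam15 (5.85) and Ccpg1os (5.90) lay little higher. The sizes and the order of all these folds are therefore uncertain. On the other side, Ebi3, which encodes a subunit shared by interleukins 27 and 35, fell by 1.78 on the log2 scale (SE 0.25) from a wild-type level of 10.28 ± 0.11 (SD, n = 4). Tnf fell by 1.43 on the log2 scale (SE 0.21), and Cd40, the receptor through which T helper cells stimulate dendritic cells, fell by 1.37 (SE 0.17). Fbln5, Idi2, Cd1d2, Gpr4, Atp6v0a1, Zc3h12d and Serpinb9b also fell, with log2 folds of -1.64 to -1.34. The size of the fall of Cd1d2 is uncertain too, since its transgenic level was 4.61. With the mean over its probe sets Idi2 was at -0.89 and did not pass (adjusted p = 0.0972 in limma). Among these 24 genes, limma's adjusted p ran from 7.00e-05 to 0.0492.

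**Figure D2:**
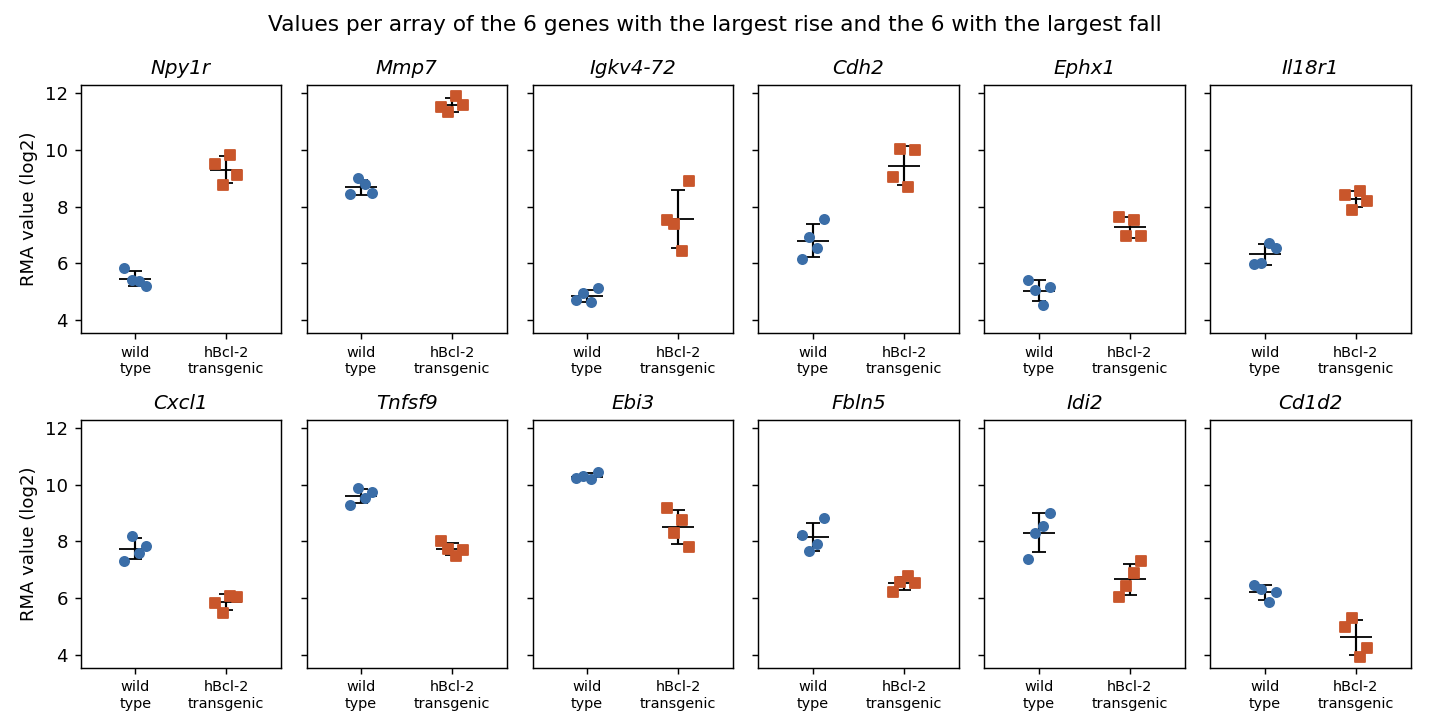
RMA values (log2) of the 6 genes with the largest rise (upper row) and the 6 with the largest fall (lower row) that the naming rule allows. Each point is an array, the long bar is the group mean and the whiskers are its SD (n = 4); in all 12 genes every transgenic array lies on the same side of every wild-type array.

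Of the 36 gene lists tested, 9 passed limma's camera test with a preset correlation between genes, 7 lower and 2 higher in transgenic arrays. None of the 36 passed with a correlation estimated from these arrays, where the smallest adjusted p was 0.506 and 2 lists had an unadjusted p below 0.05 in limma. By limma's fry, which asks whether a list moves one way on balance, 0 passed, and 26 passed its mixed test of change in either direction. Exact permutation tests of the list means gave 7 lists an unadjusted p of 0.0286, and 0 passed after adjustment. They were 6 of the 7 lower lists, all but cholesterol synthesis, and the Langerhans cell list, which was higher. With 7 lists at 0.0286, the smallest p that 70 assignments can give, the adjusted p is 0.147 however far their means differ. That 0 therefore does not speak against these lists. The count of 9 lists was also reached by other ways of dividing the arrays: 10 of the 35 divisions into 4 and 4, the real division included, gave as many. The lists are therefore described by their members.

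The list of the migratory mature dendritic cell programme, genes that cDC turn on when they mature and move to lymph nodes, had the smallest p. Of its 30 measured members, 0 rose, 7 fell and 23 did not pass, and 12 fell when adjusted over the list alone. The median log2 fold was -0.24, 27 members were negative, and limma's camera gave an adjusted p of 3.07e-09, against adjusted p = 0.506 with an estimated correlation. An exact permutation test of the list's mean gave a p of 0.0286, the smallest that 70 assignments can give. Cd40 had the lowest fold, and among the others that fell were Tnfrsf4, which encodes OX40 (-1.01, SE 0.13), Socs2, an inhibitor of cytokine signalling (-0.85, SE 0.12), Cd274, which encodes the inhibitory ligand PD-L1 (-0.75, SE 0.12), and Fscn1, the actin-bundling protein fascin (-0.69, SE 0.12). Ccr7, the chemokine receptor that guides these cells to lymph nodes, was at 12.99 ± 0.07 and 13.06 ± 0.08 (SD, n = 4) and did not pass, nor did Ccl5 (log2 fold 0.16, SE 0.10).

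**Figure D3:**
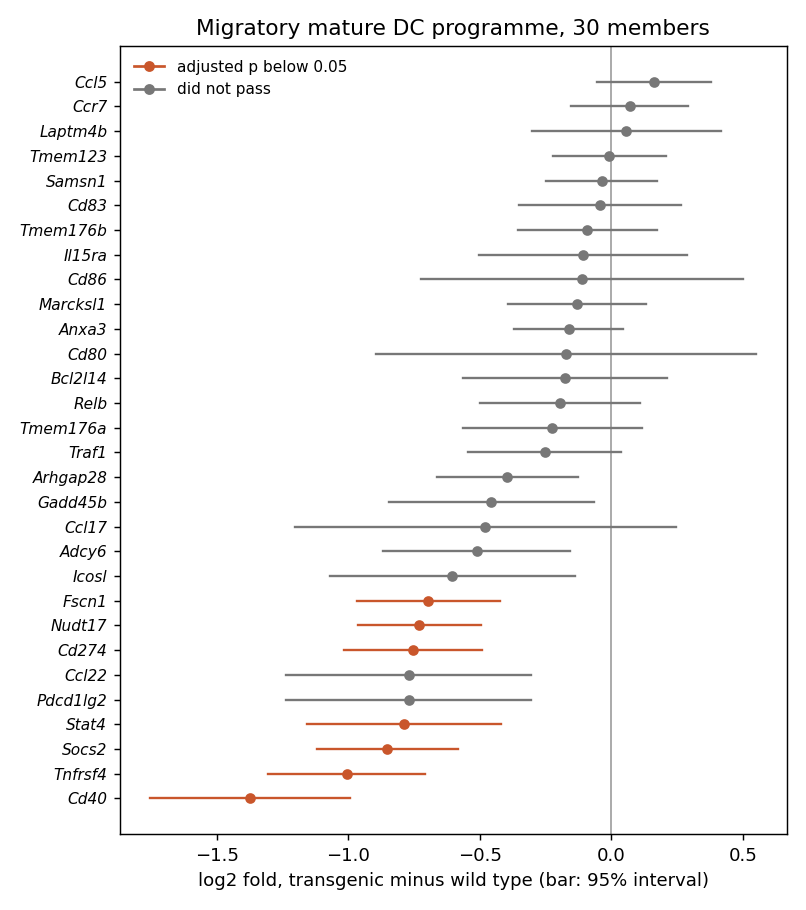
Log2 fold (transgenic minus wild type) of the 30 measured members of the migratory mature dendritic cell programme, with 95% intervals as bars. Coloured points are the 7 members with an adjusted p below 0.05 over all genes, all negative; Ccl5, Ccr7 and Laptm4b lie above 0.

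Of 31 measured inflammatory mediators and targets of NF-kB, a transcription factor that inflammatory signals activate, 0 rose, 3 fell and 28 did not pass. The 3 were Cxcl1, Tnf and Cxcl2 (log2 fold -1.21, SE 0.21), and 8 fell when adjusted over the list alone. The list's median was -0.25 (camera adjusted p = 9.24e-06 in limma, adjusted p = 0.506 with an estimated correlation). The highest member, Ccl9, was at 0.69 (SE 0.24) and did not pass. In the list of retinoic acid, tolerogenic and T helper polarising factors, 28 members were measured, of which Tnfsf13b, which encodes the B cell survival factor BAFF (log2 fold 1.25, SE 0.20, of uncertain size since its wild-type level of 5.43 was dim), and Il18 (0.92, SE 0.18) rose, and Ebi3 fell. Over that list alone, 2 rose and 7 fell. Its median was -0.21 (camera adjusted p = 0.0380 in limma, adjusted p = 0.506 with an estimated correlation), and the list no longer passed without transgenic replicate 4 (median -0.10, adjusted p = 0.233). Its median was -0.11 without wild-type replicate 1 and -0.14 without transgenic replicate 3. It also did not pass without wild-type replicates 1, 3 and 4 (adjusted p = 0.0706, 0.0690 and 0.0510 in limma), with array weights (0.136), among genes at or above the median gene (0.158) and among genes with a mean of at least 6 (0.267).

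Few genes of antigen presentation and the interferon response passed: Tapbpl and Isg15 fell and Bst2 rose. In MHC class I presentation, 19 members were measured and 1 fell, Tapbpl, which edits the peptides loaded on class I (log2 fold -0.78, SE 0.10), also when adjusted over the list alone. The median was -0.24, with 17 members negative (camera adjusted p = 9.21e-05 in limma, adjusted p = 0.506 with an estimated correlation), and -0.14 without transgenic replicate 4 or -0.15 after quantile normalization again. Pdia3 was at 0.03 and did not pass. In MHC class II presentation 0 of 19 passed, also when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.00916 in limma, adjusted p = 0.799 with an estimated correlation). The lowest member, Ciita, the master regulator of class II genes, was at -1.04 (SE 0.32; limma adjusted p = 0.158). The class II list mean was 9.31 in transgenic replicate 4 and 9.78 to 9.81 in the other transgenic arrays, and the list did not pass without that array (adjusted p = 0.168) or with array weights (0.0683). Of 35 interferon response genes, Isg15 fell (log2 fold -0.95, SE 0.20), Bst2 rose (0.76, SE 0.13) and 33 did not pass, while 2 rose and 11 fell when adjusted over the list alone. The median was -0.31 (camera adjusted p = 0.000120 in limma, adjusted p = 0.506 with an estimated correlation), and -0.17 without wild-type replicate 3.

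Of 20 measured genes of cholesterol synthesis, 1 fell, Hmgcs1, which makes the precursor of mevalonate (log2 fold -0.81, SE 0.14), and 7 fell when adjusted over the list alone. The median was -0.38, the lowest of the 36 lists (camera adjusted p = 0.000120 in limma, adjusted p = 0.506 with an estimated correlation). Of 17 p53 targets, 0 passed over all genes and 2 rose when adjusted over the list alone, Ddit4 (log2 fold 1.19, SE 0.27) and Trp53inp1 (0.85, SE 0.19). The p53 list's median was 0.21 (camera adjusted p = 0.0104 in limma, adjusted p = 0.506 with an estimated correlation). It no longer passed without transgenic replicate 1 (adjusted p = 0.103) or wild-type replicate 3 (median 0.10, adjusted p = 0.0581), or among genes at or above the median gene (median 0.10, 0.0855). Without wild-type replicate 1 its median was 0.12. Cdkn1a, the target of p53 that stops the cell cycle, was at -0.27 (SE 0.25) and did not pass.

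**Figure D4:**
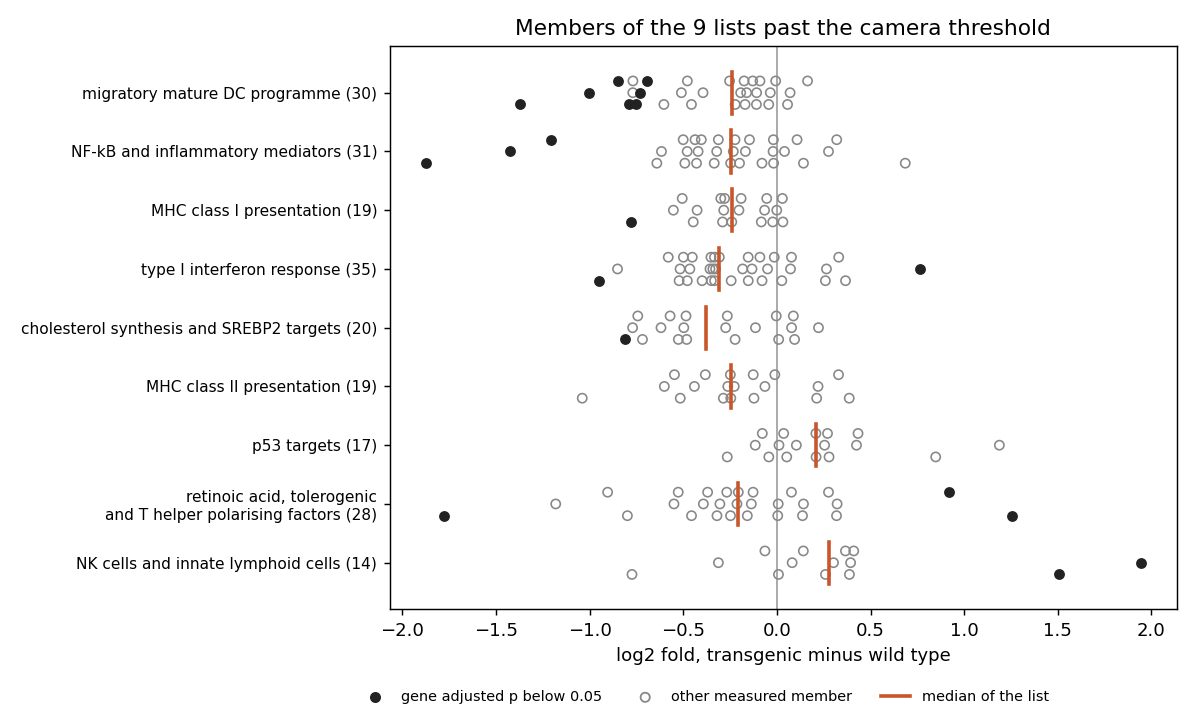
Log2 fold (transgenic minus wild type) of each measured member of the 9 lists past the camera threshold, with the number of measured members in parentheses. Filled points are members with an adjusted p below 0.05 over all genes, open points are the others and the bar is the list's median; the medians of the 7 lower lists lie between -0.38 and -0.21.

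Among the endogenous apoptosis genes only Bcl2l1, which encodes the survival protein BCL-XL, passed over all genes. It fell from 7.49 ± 0.12 to 6.71 ± 0.20 (SD, n = 4; limma adjusted p = 0.0181). It no longer passed without wild-type replicates 2, 3 or 4 (adjusted p = 0.0629, 0.0639 and 0.0549 in limma) or without variance moderation (0.0853). The other 5 measured pro-survival BCL2 family members did not pass, and Mcl1, the brightest, was at 11.66 ± 0.05 and 11.42 ± 0.16 (SD, n = 4). Adjusted over the list alone, Bcl2 rose and Bcl2l1 fell. Whether the Bcl2 probes see the human transgene was not tested, so this need not be a rise of mouse Bcl2. The dimmer Bcl2 probe set gave 4.08 and 4.06, and over the alternatives the log2 fold of Bcl2 ran from 0.36 to 0.94. Bcl2a1a (log2 fold -0.14, SE 0.13) is uncertain, since its near-identical copies can share probes. None of the 10 measured pro-apoptotic members passed, also when adjusted over the list alone. Bak1 was at -0.59 (SE 0.21), Pmaip1 at 0.38 (SE 0.11), Bcl2l11, which encodes BIM, at -0.18 (SE 0.15) and Bbc3, which encodes PUMA, at -0.23 (SE 0.14). Of 23 caspase and death receptor genes 0 passed, and Diablo (log2 fold 0.42, SE 0.11) rose and Apaf1 (-0.67, SE 0.16) fell when adjusted over the list alone. Camera's adjusted p in limma was 0.523, 0.614 and 0.590 for the 3 lists.

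Genes of cDC identity and growth factor receptors changed singly, in both directions. Among 26 genes of CD11b+ cDC, Csf1r, the receptor for macrophage colony-stimulating factor, rose (log2 fold 1.16, SE 0.19) and Esam fell (-0.62, SE 0.12), with 2 rising and 2 falling when adjusted over the list alone. Among 32 genes of dendritic cell growth factor and survival signalling, Kit, the receptor for stem cell factor (0.92, SE 0.13), Csf2rb2 (0.77, SE 0.16) and Csf1r rose and Cd40 fell, and 5 rose and 6 fell when adjusted over the list alone. None of 21 genes of CD11b- cDC (cDC1) passed, also over the list alone, and their median was -0.14. On transgenic replicate 2 the median gene of that list lay 0.78 above the mean of the other transgenic arrays. None of these 3 lists passed camera with all arrays (adjusted p = 0.671, 0.614 and 0.109 in limma). Without transgenic replicate 2 the cDC1 list passed (median -0.33, adjusted p = 0.000504), and it also passed without transgenic replicate 1 (0.0411) or wild-type replicate 1 (0.0432). Its median was nearer 0 without transgenic replicate 4 (-0.03, adjusted p = 0.726), without transgenic replicate 3 (-0.06, 0.372) and with array weights (-0.08, 0.389).

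Markers of other cell types were mostly dim, and single genes rose. Of 14 genes of NK and innate lymphoid cells, Klrd1, which encodes the receptor chain CD94, rose from 9.18 ± 0.19 to 10.68 ± 0.38 (SD, n = 4), Il18r1 rose, and 12 did not pass, with the same 2 when adjusted over the list alone. The list's median was 0.28 (camera adjusted p = 0.0438 in limma, adjusted p = 0.799 with an estimated correlation). The list no longer passed without transgenic replicate 2 (median -0.02, adjusted p = 0.644), on which its median gene lay 0.64 above the other transgenic arrays, nor without wild-type replicate 1 (median 0.03, adjusted p = 0.368) or 2 (median 0.17, adjusted p = 0.114). Its median was 0.44 without wild-type replicate 4 and 0.43 without transgenic replicate 3. Adgre1, which encodes the macrophage marker F4/80, rose (log2 fold 1.29, SE 0.19) as the only 1 of 15 macrophage genes, and Cd4 (1.18, SE 0.13) as the only 1 of 17 T cell genes, from a dim wild-type level of 5.52 that leaves the size of its fold uncertain. Among the 12 monocyte genes, Ly6c2 (1.81, SE 0.77) and Cd14 (0.74, SE 0.26) had the highest folds and did not pass; Ly6c2 was at 8.28 and 10.38 on transgenic replicates 1 and 2, and at 5.46 to 6.83 in wild type. Bst2 rose as the only 1 of 11 plasmacytoid dendritic cell genes, a list whose median was 0.35 and whose median gene lay 0.49 higher on transgenic replicate 2 than on the other transgenic arrays. In the macrophage, T cell and plasmacytoid lists the same gene rose when adjusted over the list alone, and 1 plasmacytoid gene fell. None of these 3 lists passed camera in the reported fit (adjusted p = 0.930, 0.652 and 0.0935 in limma). Without transgenic replicate 4 (0.0144) or 3 (0.0369) and with array weights (0.0375) the plasmacytoid list passed. The plasmacytoid list's median was 0.18 without transgenic replicate 2 (adjusted p = 0.531 in limma) and 0.26 without wild-type replicate 1 (0.358).

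Outside cholesterol synthesis, each list of metabolism and cell maintenance in this paragraph had 1 gene past the threshold over all genes. None of them passed camera in the reported fit. Ndufs3, a subunit of respiratory complex I, rose (log2 fold 0.69, SE 0.14) as the only 1 of 42 oxidative phosphorylation genes, also over the list alone. Abca1, the cholesterol exporter, rose (0.96, SE 0.19) among 38 genes of fatty acid and LXR lipid handling. The size of its rise is uncertain, since its wild-type level of 5.79 was dim. Eif2ak3, the stress kinase PERK, rose (0.73, SE 0.13) among 26 genes of the unfolded protein and integrated stress response. Dnm1l, which divides mitochondria, fell (-0.66, SE 0.11) among 24 genes of mitochondrial dynamics. Atg5 fell (-0.69, SE 0.14) among 28 autophagy genes, and Gclc, the first enzyme of glutathione synthesis, fell (-0.89, SE 0.15) among 21 oxidative stress genes. The proliferation marker Mki67 fell (-1.13, SE 0.22), as did Sting1, an adaptor in the sensing of cytosolic DNA (-1.02, SE 0.22), each as the only 1 past the threshold, of 38 cell cycle and 37 pattern recognition genes. Adjusted over the list alone, 4 rose and 2 fell in lipid handling, 5 rose and 1 fell in the stress response, and 2 rose and 1 fell in mitochondrial dynamics. In the same way 1 rose and 1 fell in autophagy, 0 rose and 2 fell in oxidative stress, 0 rose and 1 fell in the cell cycle, and 2 rose and 3 fell in pattern recognition. Camera's adjusted p in limma was 0.0631 for oxidative phosphorylation (median 0.10), 0.665 for lipid handling, 0.614 for the stress response and for mitochondrial dynamics, 0.930 for autophagy, 0.203 for oxidative stress, 0.712 for the cell cycle and 0.671 for pattern recognition. The oxidative phosphorylation list passed without wild-type replicate 1 (0.0374) or 4 (0.00980) or transgenic replicate 1 (0.0328), and with all arrays after quantile normalization again (0.00776) or with every probe set (0.0450). Its median was 0.04 without wild-type replicate 3 (adjusted p = 0.461 in limma). Likewise the oxidative stress list passed without transgenic replicate 1 (0.0485). Median and mean differed in sign for lipid handling (-0.05 and 0.03, camera downward), autophagy (-0.04 and 0.01, camera upward) and pattern recognition (0.05 and -0.01, camera upward).

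None of 21 glycolysis, 30 immediate early and heat shock or 35 cytosolic ribosomal protein genes passed (camera adjusted p = 0.523, 0.951 and 0.614 in limma). The same was found for 15 B cell, 9 plasma cell, 12 monocyte, 13 neutrophil, 6 Langerhans cell and 16 stromal and endothelial genes (camera adjusted p = 0.988, 0.957, 0.614, 0.614, 0.185 and 0.229 in limma), though the Langerhans cell list passed with every probe set (0.0348). With all arrays 5 of the 6 Langerhans cell genes were positive, and the list's mean was 0.21 (exact permutation p = 0.0286). Of 12 mast cell, basophil and eosinophil genes Kit rose (camera adjusted p = 0.932 in limma), also over the list alone. Adjusted over the list alone, 1 immediate early, 1 B cell and 1 plasma cell gene fell, and 0 of the others in these lists changed. Median and mean differed in sign, with camera upward, for B cells (-0.05 and 0.03), plasma cells (-0.02 and 0.04), macrophages (-0.03 and 0.03) and mast cells (-0.01 and 0.03), and the monocyte mean was 0.23 with a median of -0.0045 (0.02 after quantile normalization again). The erythroid list (3 measured) and the sex-linked list (4 measured) were too short to test.

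Of 52 genes past the threshold that the naming rule selected and that were refitted in each alternative, 22 passed whichever array was left out and 30 did not; 22 of those 30 passed in only 1 to 3 of the 8 fits, and Isg15, Sting1, Mki67, Ndufs3, Abca1, Atg5, Il18, Csf2rb2, Ceacam15, AB010352 and Serpinb9b in only 1. Leaving out transgenic replicate 4 gave 379 genes, 275 of them among the 374, and leaving out any other array lowered the count by more than 1.5 times, to 106, 115, 123 and 133 without wild-type replicates 1 to 4 and to 235, 187 and 246 without transgenic replicates 1 to 3.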

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

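In this part, the tests of the migratory members falling by 1 common amount, of the markers of NK cells, macrophages and monocytes, and of the list means over the divisions were chosen only after the result was seen.

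The number of genes past the threshold is larger than chance division of the arrays gives. Only 1 of the 35 divisions into 4 and 4, the real one, gave as many as 374 genes, and the highest of the others gave 1. For genes at an unadjusted p below 0.05 and at least 1.5-fold, likewise 1 of the 35 gave as many as 919, and the highest other gave 359. The number of lists is different: 10 of the 35 gave as many as 9, and the highest other gave 17, so chance cannot be excluded for that count. Those other divisions had at most 1 gene past the threshold, so lists can pass without single genes that pass. By the list mean, 7 of the 36 lists (6 of the lower ones and the higher Langerhans cell list) differed more in the real division than in any other, where 1.03 would fall to each division by chance, but another division reached 6. These are by construction the 7 lists with the smallest exact permutation p, so the count adds no separate support.

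The first pattern weighed is the lower migratory mature dendritic cell programme. If cells without the programme took a larger share of the transgenic pools, all members would fall by a common amount; a first test, of members above the smallest fall past the threshold (-0.695), gave 15 of 30, exactly its bound, with 11 of the 25 members with a mean below 12. It rested on a selected value, and the test that replaced it, with its bounds set when its result was known, found that the 95% intervals of 12 of the 30 leave out the common fall of -0.32, against 1.5 by chance, and 9 of those 25. That common fall was weighted over all 30, with very bright members, whose differences can be compressed, and 7 members fell further and 5 less. The count therefore does not decide against such cells. Leaving out 1 array at a time gave list medians of -0.32 to -0.20, so the lower median does not rest on 1 array. Over all alternatives, other normalizations on top of RMA included, the highest median was -0.175. Without transgenic replicate 4 the list kept an adjusted p of 6.23e-06 (median -0.20) in limma's camera. Other normalizations gave at most 2.91e-07, in a range of 2.84e-11 to 9.78e-06 over the alternatives. These p-values hold only at the preset correlation. A change in cell makeup, as the whole or part of the cause, and cells that carry part of the programme stay open. An effect of the transgene may account for the lower programme only as a hypothesis. With an estimated correlation the list did not pass camera (adjusted p = 0.506), and litter and sorting day are untested.

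The second pattern is the rise of single genes from the marker lists of other cells, with Csf1r, which is in the CD11b+ cDC list. Whether the sorted cDC themselves raised these genes was not tested. Macrophages could bring Adgre1, and Csf1r with it, but they would bring their other abundant transcripts too. The 95% intervals of 3 of the 3 other macrophage members with a mean of at least 6, C1qa, C1qb and Cd68, lie below that of Adgre1. Cd68 was at 9.85 in wild-type and 10.18 in transgenic arrays, too bright to show a small share. Without it fewer than the 3 members that the test needed remain, so the count does not decide on macrophages. For monocytes the intervals of 2 of 5 such members lay below that of Adgre1. For NK or innate lymphoid cells 3 of 7 lay below that of Klrd1. These counts decide neither. Ly6c2 was higher by 1.81 and Cd14 by 0.74. Nkg7 was at 6.79 and 7.16 and Gzma at 6.05 and 6.45 in wild-type and transgenic arrays. Lyz2, like Cd68, is too bright to show a small share. A first count over all members (9 of 13 for NK cells, 14 of 14 for macrophages, 8 of 12 for monocytes) rested partly on genes near the dim end, which exclude nothing. The sort was for CD103+ CD11b+ cDC. Klrd1 was highest on transgenic replicate 4 (11.18) and Il18r1 on replicate 3 (8.54). The median gene of the NK list lay lower there (-0.28 and -0.39). On replicate 2 that median lay 0.64 higher, while Il18r1 was the lowest of the transgenic arrays (7.88) and Klrd1 was at 10.78. With 4 arrays and many dim members, this differing course does not decide on NK cells. B cells and plasma cells were not weighed here. Macrophages, monocytes and NK cells in the transgenic pools stay open, as does a varying share of cDC1 and plasmacytoid cells. The cDC1 and plasmacytoid lists were higher on transgenic replicates 2 (0.78 and 0.49) and 1 (0.33 and 0.28) and lower on 3 and 4.

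The third pattern is transgenic replicate 4. Its range of values was narrower. After quantile normalization was applied again its mean correlation with the other transgenic arrays was 0.974 (0.9744), still below the 0.980 to 0.983 of the others. A correlation does not change when values are rescaled evenly, so this test could not decide whether the narrower range set the array apart. Cells of another type would raise their markers there, and the largest median deviation of a marker list on that array was 0.26 (0.2558, mast cells, basophils and eosinophils). That argues at most against a large share of added cells of a listed type. The markers were mostly dim, and the median over a list can miss a small share, so a small share stays open. The lists of plasmacytoid cells (-0.60), cDC1 (-0.51), B cells (-0.33) and NK cells (-0.28) lay lower there, so a smaller share of such cells in that pool stays open. RNA quality and yield of that pool stay open, as no value bears on them, and no biological difference between the pools of a group was tested.

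A single array lay far from the other 3 of its group in 12 of the 212 groups of values examined, where chance gives about 11, or 1 in 20 groups. The gap to the nearest array, as a share of the group's range, was 0.951 for the mean of the MHC class II list in transgenic replicate 4 (9.31 against 9.78 to 9.81). In the same array it was 0.944 for Il18 (8.40 against 7.63 to 7.68), 0.885 for Uhrf1 (6.77 against 7.67 to 7.78) and 0.835 for Itgax (8.80 against 9.32 to 9.42). It was 0.932 for Cd1d1 in transgenic replicate 2 and 0.830 for Ndufs3 in transgenic replicate 1. Among wild-type arrays it was 0.944 for Ccr7 and 0.874 for Bcl2a1a in replicate 2, 0.859 for Eif2ak3 in replicate 3, and 0.929 for Fas, 0.891 for Ccpg1os and 0.876 for Csf1r in replicate 4.

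Probe sets that name no gene or several genes were outside the comparison. When all probe sets were fitted together in limma, 54 of these 10869 passed the threshold, 19 higher and 35 lower in transgenic arrays.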

How the results depend on the processing

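All alternatives here were planned; none was chosen after the result was seen. Of the 52 genes past the threshold that the naming rule selected and that were refitted here, 0 changed direction in any setting, and 22 passed whichever array was left out, among them Npy1r, Mmp7, Sox4, Cxcl1, Tnfsf9, Ebi3, Cd40, Tnf, Klrd1 and Tapbpl. The other 30 lost the threshold without at least 1 array, and 22 of them passed in only 1 to 3 of the 8 fits; 26 to 43 of the 52 passed per fit. In the other settings they passed in 481 comparisons and not in 87. Bcl2l1 did not pass with the replicate number as a block (adjusted p = 0.0670 in limma). Bcl2 did not pass in any setting. The 374 genes became 35 (16 higher, 19 lower) without variance moderation, which leaves only the arrays' own spread per gene. Lower genes were 308 among genes with a mean of at least 6, where fewer genes were tested, and higher genes 283 with array weights; the cause was not tested. Wider thresholds gave 747 (adjusted p below 0.1) and 1896 (below 0.25), and 178 of the 919 genes differed at least 2-fold. The lists past the threshold became 0 with an estimated correlation and 0 by fry. Without 1 array, which leaves fewer samples, the count ran from 106 to 379, higher from 55 to 216 and lower from 51 to 163. It was 106, 115, 123 and 133 without wild-type replicates 1 to 4, and 235, 187, 246 and 379 without transgenic replicates 1 to 4. Called lists kept the threshold in 62 of these fits and lost it in 10 (4 lists), and in the other settings they kept it in 94 and lost it in 5, with array weights (2 lists) and dim-gene filters (2 lists); the cause was not tested. With the replicate number as a block there were 187 genes (95 higher, 92 lower), and 9 lists passed. The labels do not say whether the numbers pair the arrays. Deviations of same-numbered arrays correlated at -0.03, -0.03, 0.08 and -0.02, and only number 3 was the best partner on both sides. Such correlations over all genes cannot exclude a shared litter or sorting day. These changed sign: Itgam, reported at 0.01, was at -0.0072 with quantile normalization again and ran from -0.0526 to 0.0796 without 1 array, and Pdia3, reported at 0.03, ran from -0.0282 to 0.0825, and the median of the NK and innate lymphoid list, reported at 0.28, ran from -0.02 to 0.44. The medians of 13 lists that did not pass, all reported within 0.10 of 0, changed sign in at least 1 setting, among them B cells (-0.14 to 0.13), plasma cells (-0.11 to 0.18), macrophages (-0.10 to 0.03) and monocytes (-0.10 to 0.44); the cause was not tested. Dim genes such as Itgae and Itgam lie where signal is hard to tell from background.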

Other observations

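In this part, the tests of actin cytoskeleton, ribosome biogenesis, primary cilium, neighbouring genes and symbol families were chosen only after the result was seen, and the genes named here were chosen after their values were seen.

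Genes of the actin cytoskeleton stood out among the falls, with 10 of 52 measured members lower, among them Flna, Actn1, Vasp and Myh9, and 0 higher. Of the 42 members that did not pass, 30 were negative and the median was -0.26 (-0.2579); camera gave p = 2.08e-06 in limma at the preset correlation and p = 0.0542 with an estimated one, and an exact permutation test p = 0.0286, the smallest it can give. A joint fall of these genes is a hypothesis that the estimated correlation leaves open. Genes of ribosome biogenesis may rise together: 6 of 64 rose, among them Nop58 and Wdr75, and of the 58 others 50 were positive, with a median of 0.24 (0.2392), but camera's p was 3.52e-08 in limma at the preset correlation and 0.0893 with an estimated one, and an exact permutation test gave p = 0.0571. For the primary cilium, 5 of 46 genes rose and 1 fell, and the median of the 40 others was 0.09 (0.094). An exact permutation test of those 40 gave p = 0.114, and camera in limma 0.0511, so a rise of the group was not borne out.

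Among 241 families of genes with a shared symbol, immunoglobulin kappa variable genes had the smallest camera p, with 13 genes, 2 of which rose, and a median of 0.58 (adjusted p = 0.00200 in limma, adjusted p = 0.766 with an estimated correlation). Ighg3 and Jchain had log2 folds of 2.09 (SE 0.50) and 0.88 (SE 0.30) and did not pass. The B cell and plasma cell lists had medians of -0.05 and -0.02 and did not pass camera. Whether RNA of B cells or plasma cells in the pools brought the immunoglobulin transcripts was not tested and stays open. Genes of mitochondrial ribosomal small subunits (28, median 0.22, 1 rose), methyltransferase-like genes (24, median 0.16, 0 rose) and tRNA methyltransferases (15, median 0.24, 1 rose) had an adjusted p of 0.0260 in limma, and 0.766 with an estimated correlation.

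A transgene can carry neighbouring genes of its insertion site or of the founder's chromosome along with it. At most 4 genes past the threshold lay among 11 neighbouring genes, and 0.154 of 1000 random orders reached as many, so no cluster of changed genes was found beyond chance. A region with fewer changed genes would be missed.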
